A study of Drosophila melanogaster x Drosophila sechellia and Drosophila melanogaster
Drosophila sechellia and Drosophila melanogaster with 4 samples.

How the data were processed

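The deposited files are lists of aligned reads, which is a unit other than counts, signal or scores: the authors gave 1 line per read with its start, end, strand and name, and no score. There were 6 such lists for the 4 libraries, 1 for each species to which reads had been assigned. The genome build dm3 comes from the submitters' processing notes, and sequence names in the lists are those of dm3. Sechellia reads are placed on the same coordinates. The aligner, the mismatch limit and the rule that assigned a read to a species are not given in the sources used here. Per the labels the libraries were poly-A selected, primed at random and sequenced from both ends, with an insert of about 350 ± 20 bp for the hybrid and the mixture. The most common read span was 37 bp in the hybrid and mixed libraries and 27 bp in the separate ones. Spans other than the most common made up part of the sechellia lists only, where 94.6% of hybrid and 94.3% of mixed reads had it. Read names found in both species lists of 1 library made up 0.420% in the hybrid and 0.394% in the mixture. Distinct positions made up 28.0% and 28.9% of the hybrid melanogaster and sechellia reads, 41.6% and 38.8% of the mixed ones, and 32.9% and 28.1% of the separate ones.

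The samples were grouped by their labels into F1 hybrid, mixed parental RNA, melanogaster alone and sechellia alone, with 1 library each. The design, the tests, the rule for named windows and most alternatives were fixed before the data were examined. The gene annotation at hand was of a later build than dm3, so coordinates were not converted, no gene was named and the fixed gene lists and cell type markers were not analysed here. Reads were counted by their midpoint in non-overlapping windows of 1000 bp, the fallback fixed for this case. A window was tested with at least 20 assigned reads in the mixed and in the hybrid library and at least 5 reads of each species over all libraries. That gave 34965 windows, and 327 windows with enough reads but under 5 of 1 species were left out.

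The log2 ratio of melanogaster to sechellia reads, with 0.5 reads added to each, was centred on the library-wide share of melanogaster reads in tested windows, 52.5% in the mixture and 52.1% in the hybrid. Mixed and hybrid ratios were tested with a two-sided exact binomial test against that share. Their difference was tested with a two-sided Fisher's exact test, with hybrid reads thinned by a binomial draw (seed 20) to match the centre. All were adjusted by Benjamini-Hochberg at 0.005 over the tested windows of each comparison. Conserved windows passed no test. Cis only windows passed the mixed and hybrid tests, trans only windows the mixed test and that of the difference, and compensatory windows the hybrid test and that of the difference. Windows that passed all 3 were split by whether the hybrid ratio and the difference had the same sign, and the rest were ambiguous. The hybrid total in CPM, scaled to all assigned reads in tested windows of the library, was compared with each parent in CPM of the reads of its species in the mixed library, with a limit of 1.25-fold and no test across flies. Intervals are exact (Clopper-Pearson) at 95% and cover counting error only, since reads without molecular identifiers are not independent molecules. The tests compare libraries, not conditions.

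Named windows were, for each ratio and for the difference, the 10 with the largest value in each direction among those past the test. They needed at least 200 reads in both libraries, at least 20 reads of each species, and for the mixed ratio the same sign in the separate libraries. For totals they were the 10 furthest above and the 10 furthest below both parents, with at least 200 reads in the hybrid or mixed library and the same side with the separate libraries. Regions join windows at least 2-fold beyond both parents that lie at most 2 windows apart, a step added after the data were seen. CPM of a region cover all its windows.

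The tests were tried on simulated data made from the window totals, with 200 windows changed. A cis change of 2-fold was recovered by the mixed test in 51.0% and by the hybrid test in 67.0% of the changed windows. A trans change was recovered by the test of the difference in 32.5% at 2-fold and 73.5% at 4-fold, and at most 3 unchanged windows were called. The simulated counts held counting error only, without duplicate reads or spread between libraries. Few false calls were therefore built in, and they do not give the rate of false calls in the real reads. The spread between mixed and separate ratios beyond counting error was an SD of 0.137 in log2 per ratio, estimated on 22340 windows with at least 100 reads, and it gave a correlation between reads of 0.00227 for beta-binomial tests.

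Alternatives fixed beforehand were a minimum of 1 or 100 reads, ratios centred on the median window or not at all, and reads of the same start, end and strand counted once. Others were parents from the separate libraries, libraries thinned to equal totals in each window, a threshold of 0.05 and at least 1.5-fold differences. The last were beta-binomial tests and the hybrid reads split at random between the allele ratio and the difference. For totals they were limits of 1.5-fold and 2-fold and scaling to a median of 0. In the beta-binomial setting the difference was tested with a normal test of its log2 value. That test added the spread between mixed and separate ratios to the counting error. Added after the data were seen were mates of a fragment counted once per window, each flow cell alone, the mixed library without lane 8 of flow cell 130MNEAAXX, placed arms only, and regions with positions counted once. Counting used a program in C, and all else was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.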

Results

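Poly-A selected RNA from whole flies was sequenced as 4 libraries, with 1 library in each of 4 groups. The groups were the F1 hybrid of Drosophila melanogaster and Drosophila sechellia, a mixture of RNA from both parental species, D. melanogaster alone and D. sechellia alone. The hybrid and mixed libraries came from adult females aged 0 to 2 days after eclosion, and the labels give no sex or age for the separate libraries. The hybrid library held 19351655 reads assigned to melanogaster and 17781435 assigned to sechellia. The mixed library held 10439200 and 9329883. The separate libraries held 17434214 melanogaster reads and 19906835 sechellia reads. Reads were counted in windows of 1000 bp of the dm3 melanogaster genome, because no gene annotation of that build was used here. Of 90743 windows with a read, 34965 were tested, and they held 97.8% of the mixed and 98.8% of the hybrid reads. The median tested window held 171 mixed reads (quartiles 66 and 395) and 245 hybrid reads (quartiles 99 and 622). For a window with even counts, the exact (Clopper-Pearson) 95% interval of the melanogaster share was 27.2% to 72.8% at 20 reads and 46.9% to 53.1% at 1000 reads. With 1 library per group there was no check against replicate flies. The tests below are exact tests on the reads of these libraries, intervals cover counting error only, and neighbouring windows are not independent replicates.

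The mixed library asked how far the parental species differ in RNA level. Windows were ranked here only with at least 200 reads in both the mixed and hybrid libraries and at least 20 reads of each species in these libraries together. Among them, the window with the largest excess of melanogaster reads was X 7930001–7931000, with 7029 melanogaster and 10 sechellia reads, a centred log2 ratio of 9.24 (95% interval 8.43 to 10.37). It was followed by 2L 4950001–4951000 at 8.30 (7.71 to 9.05), 3L 9634001–9635000 at 8.08 (7.19 to 9.38) and 3L 6032001–6033000 at 7.92 (7.52 to 8.38). Among windows that met these read minimums, the largest excess of sechellia reads was in 3L 9083001–9084000, with 2 melanogaster and 1118 sechellia reads, a log2 ratio of -8.95 (-12.32 to -7.42). Its neighbours 3L 9084001–9085000 and 3L 9082001–9083000 stood at -7.13 and -7.08, and 2R 4821001–4822000 and 2R 7302001–7303000 stood at -7.95 and -7.48. Windows were named here only where the separate libraries gave the same sign, and there X 7930001–7931000 stood at 8.28 and 3L 9083001–9084000 at -5.80. With reads of the same position counted once, X 7930001–7931000 stood at 6.19 in the mixture, 2L 4950001–4951000 at 5.10, 3L 6032001–6033000 at 4.45 and 3L 9083001–9084000 at -7.86. That setting caps a window at the number of its positions, which compresses large ratios of abundant windows.

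Across all tested windows, 17062 (48.8%) differed between the species by the two-sided exact binomial test at a Benjamini-Hochberg adjusted p of 0.005. Melanogaster was higher in 10629 of them and sechellia in 6433, and 10062 differed at least 2-fold. The median absolute difference over tested windows was 1.64-fold. Ratios were centred on the library-wide share of melanogaster reads (52.5%), which left the median window at a log2 ratio of 0.19. With the median window set to 0 instead, melanogaster was higher in 50.3% of the windows past the test rather than 62.3%. Reads of 130MNEAAXX, 1 of the 2 flow cells that carried this library, gave 10191 windows when used without the other.

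The separate libraries gave the only repeat of the species ratio. At X 7930001–7931000 and at 2R 7233001–7234000, both named under that condition, they held 9948 melanogaster against 36 sechellia reads and 6427 against 179. Of the 17062 windows called in the mixed library, 16858 (98.8%) had the same sign in the separate libraries. Across windows the log2 ratios correlated at Pearson 0.881 and Spearman 0.876, and the SD of their difference was 0.58. In the 14837 windows with at least 200 reads in both the mixed and hybrid libraries, these values were 0.957, 0.944 and 0.31. The reads of the separate libraries were 27 bp long and those of the mixture 37 bp.

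In the F1 hybrid, where both alleles share the same cells, the allele ratio reads out cis-regulatory divergence. The hybrid kept the melanogaster excess at X 7930001–7931000, with a log2 ratio of 10.43 (95% interval 9.85 to 11.15), at 2L 4950001–4951000 with 9.94 and at 3L 6032001–6033000 with 9.17 (8.66 to 9.78). It kept the sechellia excess across 3L 9082001–9086000, where the 4 windows stood between -6.76 and -5.73. Among windows that met the read minimums for naming, the one furthest towards sechellia was 3R 24495001–24496000, at -6.86 (-7.45 to -6.36) in the hybrid and -5.88 in the mixture. Other windows named in the mixture had smaller ratios in the hybrid, as 2R 7302001–7303000 went from -7.48 to -2.96, 2L 15285001–15286000 from -6.80 to -1.86, X 250001–251000 from -7.14 to -3.89 and 3L 9634001–9635000 from 8.08 to 5.63. At 2L 1133001–1134000 the log2 ratio was 2.12 in the mixture and 7.32 (6.37 to 8.74) in the hybrid. The 10 windows named furthest towards melanogaster also included U 5293001–5294000 (9.17), U 5300001–5301000 (8.97), U 5290001–5291000 (7.90), M 5001–6000 (7.67) and U 5291001–5292000 (7.27). Mitochondrial RNA is inherited through the mother, so its ratio does not read out cis-regulatory divergence. The U windows named here shifted towards melanogaster in the hybrid as it did (below), so their ratios are not read that way either. With positions counted once the hybrid ratios were smaller, at 5.85 for X 7930001–7931000, 6.65 for 2L 4950001–4951000, 5.34 for 3L 6032001–6033000, 6.21 for 2L 1133001–1134000 and -4.74 for 3R 24495001–24496000.

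The allele ratio passed the test in 9956 windows (28.5%), with melanogaster higher in 4538 and sechellia higher in 5418, and 3404 of them differed at least 2-fold. The median absolute difference was 1.26-fold, against 1.64-fold between the species. The balance of directions turned with the centring and with the counting of reads. Melanogaster was higher in 45.6% of the called windows here, in 51.0% with the median window at 0, in 62.1% with no centring and in 55.6% with reads of the same position counted once. In the windows with at least 200 reads in both libraries, 42.3% passed the test in the hybrid and 67.8% in the mixture, although the hybrid held more reads. At least 2-fold differences, whether or not past the test, were found in 6.56% of the windows with at least 200 reads in the hybrid and in 27.7% in the mixture. The count fell to 3882 with positions counted once, to 5078 with a beta-binomial test and to 2332 with reads of flow cell 130MNEAAXX only.

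**Figure D1:**
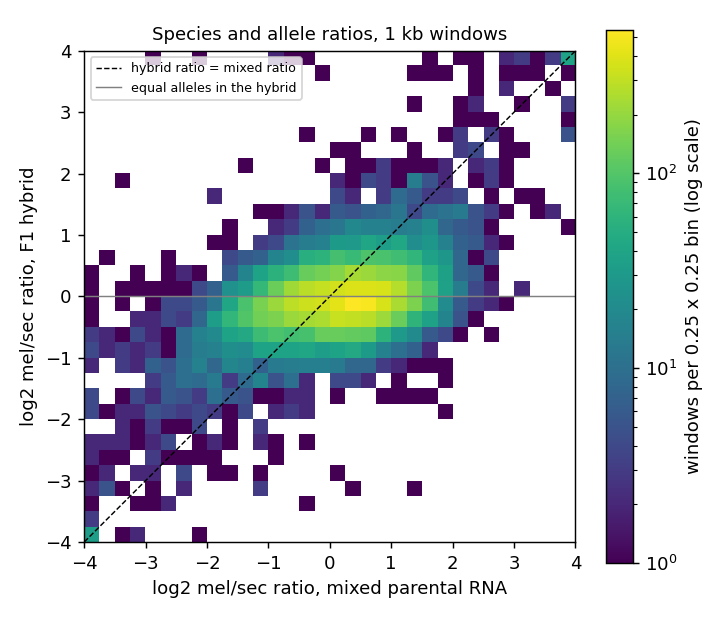
Centred log2 ratio of melanogaster to sechellia reads in the mixed library (x axis) and in the F1 hybrid (y axis) over 1 kb windows with at least 200 reads in both, with the number of windows per bin as colour on a log scale, a dashed line at equal ratios and a grey line at equal alleles. The 14837 windows spread with an SD of 1.07 along the x axis and 0.75 along the y axis, and the outermost bins hold the values beyond the axes.

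The difference between the mixed and the hybrid ratio serves as the readout of trans-regulatory divergence. With 1 library of each, any other difference between the libraries enters it too. On the mitochondrial sequence, so does inheritance through the mother, and the U windows named for this difference shifted the same way (below). The windows called below are therefore not all shown to differ by trans regulation. Among windows that met the read minimums for naming, the one furthest towards a melanogaster excess in the mixture was 2R 12126001–12127000. Its log2 ratio was 1.49 (1.15 to 1.85) in the mixture and -3.17 (-3.87 to -2.58) in the hybrid. At 2R 15585001–15586000 it was 5.02 in the mixture and 1.16 in the hybrid, and at 3R 19514001–19515000 it was 1.93 and -1.82. Among named windows on the chromosome arms, the differences furthest in the other direction were at 2L 1133001–1134000, at -5.20, and at X 12385001–12386000, at -5.11. At the latter the mixture held 37 melanogaster and 327 sechellia reads and the hybrid 2326 and 596. The remaining 8 of the 10 windows named in that direction lay on the mitochondrial sequence or on the unplaced sequence U. With positions counted once these 8 stood between -3.74 and -1.66, where U 5293001–5294000 no longer passed the test, and 2R 12126001–12127000, 2L 1133001–1134000 and X 12385001–12386000 stood at 3.84, -4.80 and -4.01.

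Fisher's exact test called 11941 windows (34.2%), with the mixed ratio further towards melanogaster in 7495 and further towards sechellia in 4446. A total of 7153 windows differed at least 2-fold. With the median window at 0 the first group made up 44.5% of the called windows, and with reads of the same position counted once 46.6%, against 62.8% here, so the predominant direction turned. The number of windows fell to 4891 with positions counted once and to 3725 with flow cell 130MNEAAXX only. In the beta-binomial setting, a normal test of the log2 difference with added spread gave 7328.

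The 3 tests together gave 7 classes. They rest on which tests passed, and a test that did not pass does not show that values were equal. A total of 6972 windows (19.9%) passed the tests between the species and between the libraries but not that of the hybrid alleles, a class termed trans only. Another 3187 windows (9.11%) passed the tests between the species and between the alleles but not that between the libraries, termed cis only. The window 3L 9082001–9083000 was cis only, with a log2 difference of -0.32 and an adjusted p of 0.806, and it had the same class with the separate libraries as parents. X 7930001–7931000 was cis only with a difference of 2.27-fold (adjusted p of 0.140), but with the separate libraries the difference was 4.43-fold and passed the test (2.8e-07). In 1635 windows (4.68%), 3L 9083001–9084000 (cis only with the separate libraries) and 2R 7302001–7303000 among them, all 3 tests passed with both components in the same direction. In 1551 windows (4.44%), 2R 12126001–12127000 and X 12385001–12386000 among them, they passed with opposing directions. Compensatory windows, which passed the tests of the hybrid alleles and of the difference but not that between the species, numbered 1355 (3.88%), 13892 (39.7%) passed no test and 6373 (18.2%) were ambiguous. With at least 200 reads in both libraries, trans only made up 29.6% and cis only 11.5% of 14837 windows. Opposing and compensatory windows numbered 951 and 652 when separate random parts of the hybrid reads served the allele ratio and the difference. They numbered 339 and 629 in the beta-binomial setting, with its normal test of the difference, which left 390 windows in the same direction. Trans only and cis only numbered 3759 and 1767 with positions counted once, of which 2721 and 1432 had the same class here. That setting gave 298 windows in the same direction, 158 opposing and 372 compensatory. They numbered 2641 and 1094 with flow cell 130MNEAAXX only, of which 1611 and 667 had the same class here.

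Among the 10060 windows past the test between the species with at least 200 reads in both libraries, the cis share had a median of 24.4% (quartiles 12.7% and 44.9%). The cis share is the absolute hybrid log2 ratio over the sum of the absolute hybrid ratio and the absolute difference. The mixed ratio enters this share and also selects and groups the windows, so part of its course may be built in. The share varied with the size of the species difference, first falling and then rising. It was 33.2% in the 1347 windows with an absolute mixed log2 ratio under 0.5, 23.7% between 0.5 and 1, 19.5% between 1 and 1.5, 21.1% between 1.5 and 2, 44.8% between 2 and 3, and 72.3% in the 196 windows at 3 or above. In the latter group the share differed between named windows, with 97.4% at 3R 25748001–25749000, 95.5% at 3L 9082001–9083000, 39.6% at 2R 7302001–7303000, 27.3% at 2L 15285001–15286000 and 23.1% at 2R 15585001–15586000. With the separate libraries as parents these shares were 72.2%, 99.6%, 38.5%, 26.8% and 24.6%, and 3R 25748001–25749000 was no longer cis only. The group also holds windows with few reads of 1 species, such as X 7930001–7931000 with 7029 melanogaster and 10 sechellia reads in the mixture.

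**Figure D2:**
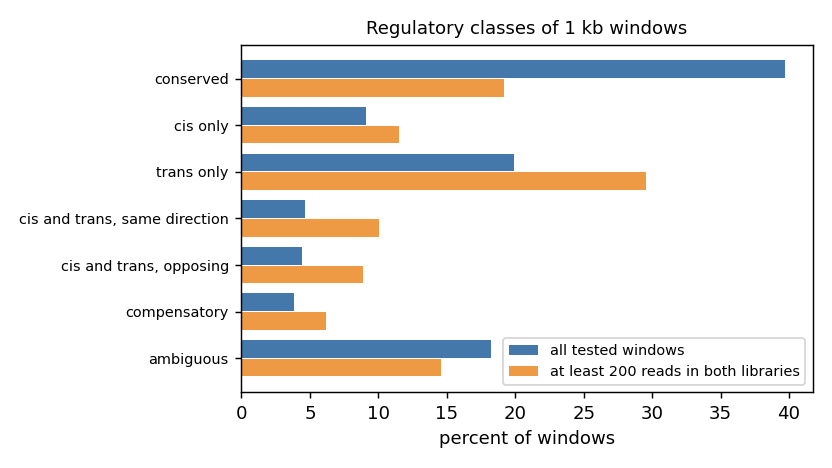
Percent of windows in each of the 7 regulatory classes, as bars for all 34965 tested windows and for the 14837 windows with at least 200 reads in the mixed and hybrid libraries. Trans only holds 19.9% and 29.6% of them, and cis only 9.11% and 11.5%.

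The hybrid total, both alleles together in CPM (reads scaled to the size of the library), was set against each parent in the mixed library. In the hybrid, 3L 12122001–12125000 stood at 3861 CPM against 152 in melanogaster and 508 in sechellia, 25.4-fold and 7.60-fold higher, which became 3.17-fold and 1.41-fold with reads of the same position counted once. Region 3L 14087001–14092000 stood at 3626 against 61.0 and 679, and 2L 899001–902000 at 857 against 42.4 and 243. With positions counted once, these regions stood 1.46-fold and 1.47-fold above sechellia and 9.17-fold and 6.30-fold above melanogaster. In the other direction, 2L 5957001–5961000 held 4.09 CPM in the hybrid against 2801 in melanogaster and 396 in sechellia. Region X 14092001–14094000 held 1.28 against 918 and 188, and 2R 18691001–18693000 held 2.59 against 1097 and 197. With positions counted once, sechellia stood 20.9-fold, 61.9-fold and 30.4-fold above the hybrid in these 3 regions.

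These regions join windows at least 2-fold beyond both parents, and they were chosen after their values were seen. The windows named by the rule fixed beforehand lay partly in the same places. Highest above the nearer parent was 2L 9747001–9748000, with a log2 ratio of 3.72 (95% interval 3.11 to 4.50) to melanogaster and 4.00 (3.30 to 4.93) to sechellia. It was followed by 3L 16298001–16299000 at 3.55 (3.16 to 4.00) to melanogaster, and by 3L 12122001–12123000 and 3L 12123001–12124000 at 3.24 and 3.04 to sechellia. With positions counted once these 4 windows stood at 2.07, 2.23, 0.83 and 0.51 to the nearer parent. Furthest below both was X 14092001–14093000, at -7.28 (-7.96 to -6.73) to sechellia and -9.44 (-10.12 to -8.90) to melanogaster. The remaining windows furthest below stood between -7.03 and -6.10 to the nearer parent, in 2L 5957001–5961000, 3R 10726001–10727000, 3R 4761001–4762000, 2R 18691001–18693000, X 14093001–14094000 and X 5206001–5207000. With the separate libraries as parents, X 14092001–14093000 stood at -6.84 to the nearer parent and 2L 9747001–9748000 at 3.87, and with positions counted once X 14092001–14093000 stood at -6.03.

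Counted with a limit of 25% above or below a parent, the hybrid was like sechellia alone in 11413 windows (32.6%) and like melanogaster alone in 3774 (10.8%). It lay between the parents in 4727, within the limit of both in 3996, above both in 3240 (9.27%) and below both in 7815 (22.4%). No test across flies was possible for these classes. In windows with at least 200 reads the log2 ratio of the hybrid to sechellia differed between the flow cells with an SD of 0.51 and that to melanogaster with an SD of 0.49, which is wider than the limit. The log2 ratio to sechellia had a median of -0.14 and an interquartile range of 0.71, and that to melanogaster a median of -0.23 and an interquartile range of 1.49. With the separate libraries as parents the medians were 0.07 and -0.03 and the ranges 0.75 and 1.54, and windows above both (6421) then outnumbered those below both (5451). Many windows changed class with these parents. The same class was kept by 5397 of the 11413 like sechellia, 999 of the 3774 like melanogaster, 1759 of the 4727 between, 1277 of the 3996 within both, 2486 of the 3240 above both and 3714 of the 7815 below both. Above both also outnumbered below both with positions counted once, at 4817 against 3298. With the ratios scaled to a median of 0, the counts were 5136 above and 5405 below, and with flow cell 130MNEAAXX only 4818 lay below. At a limit of 2-fold, 410 windows lay above and 1473 below.

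**Figure D3:**
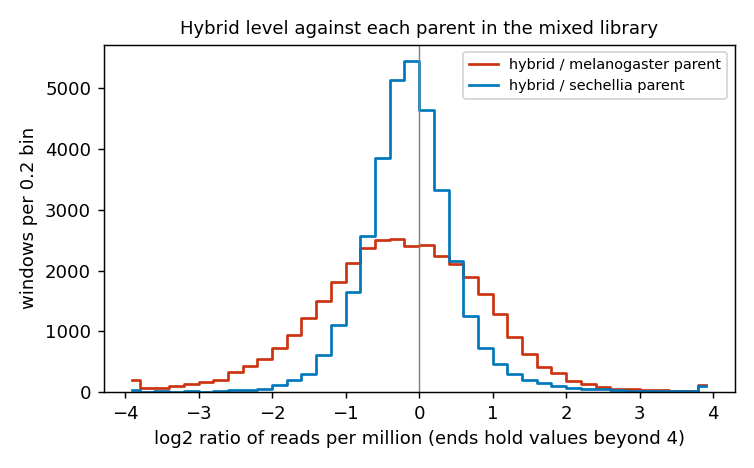
Number of windows (y axis) by the log2 ratio of CPM in the F1 hybrid to each parent of the mixed library (x axis, outer bins hold values beyond the axis), as 1 line per parent over 34965 windows. The ratio to sechellia is narrower, with an interquartile range of 0.71 against 1.49 for melanogaster.

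Windows at least 2-fold beyond both parents, on the same side with the separate libraries and with at least 200 reads in the hybrid or mixed library, numbered 330 above and 693 below. They joined into 204 and 418 regions. The regions above both held 3.52% of the hybrid reads, against 0.745% of the melanogaster and 1.14% of the sechellia reads of the mixture. Those below both held 0.968% of the hybrid reads, against 5.88% and 2.64%. Of the 693 windows below both, 661 had a mixed ratio towards melanogaster, with a median log2 of 1.42, while 243 of the 330 above both had one towards sechellia. In 60 windows the hybrid was at least 8-fold below both parents, and in 5 it was at least 8-fold above both. Chromosome 4 held none of the windows at least 2-fold beyond both. Among abundant regions, X 9945001–9947000 stood at 4269 CPM in the hybrid against 11237 in melanogaster and 9237 in sechellia, and 3L 3193001–3197000 at 681 against 3741 and 2440. With positions counted once, sechellia stood 1.49-fold and 1.92-fold above the hybrid in these regions. Of the 204 regions above both, 199 then stayed above both and 102 at least 2-fold, and all 418 below both stayed below both, 129 of them at least 2-fold.

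**Figure D4:**
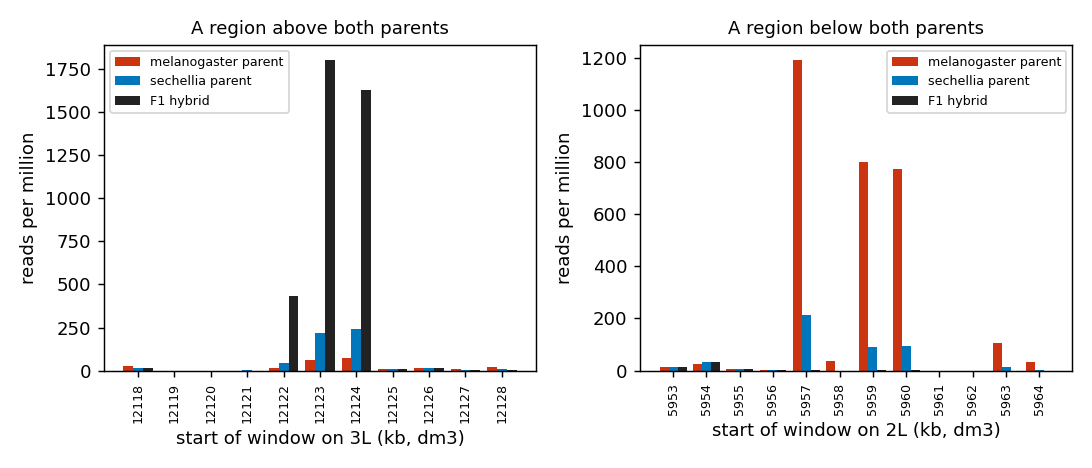
CPM (y axis) in 1 kb windows along 3L around 12122001–12125000 and along 2L around 5957001–5961000 (x axis, start of the window in kb, dm3), as bars for the melanogaster and sechellia parents of the mixed library and the F1 hybrid. Over the regions the hybrid stands at 3861 against 152 and 508 on 3L (671 against 212 and 475 with positions counted once, not drawn) and at 4.09 against 2801 and 396 on 2L.

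Mitochondrial RNA, which flies inherit through the mother, carried melanogaster sequence in the hybrid. Of the reads on the mitochondrial sequence, 139443 in the hybrid were assigned to melanogaster and 1176 to sechellia, a melanogaster share of 99.2% (exact 95% interval 99.1% to 99.2%). In the mixed library the share was 35.9% (35.6% to 36.1%), from 45948 and 82115 reads. On the unplaced sequence U, window 5290001–5291000 behaved alike, with a melanogaster share of 99.6% in the hybrid and 45.6% in the mixture. Window U 5301001–5302000 held 149771 sechellia reads in the mixture and 3988 in the hybrid. Of the former, 115460 came from lane 8 of flow cell 130MNEAAXX. They made up 51945 CPM of its sechellia reads, against 1110 to 6889 in the other 3 lanes. Lane 8 alone did not make the excess over the hybrid. On FC30B79 the hybrid lanes stood at 172 to 189 CPM and the mixed lanes at 6889 and 6569. The log2 ratio of the hybrid total to sechellia was -6.99 with the sechellia-alone library and -6.87 with the mixture.

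Among the chromosome arms, the X stood furthest towards melanogaster in the mixture and chromosome 4 furthest towards sechellia. The median mixed log2 ratio was 0.31 on the X and -0.09 on chromosome 4, against 0.12 to 0.22 on 2L, 2R, 3L and 3R. With the median window of all at 0, the medians were 0.12 and -0.28. Random sets of the same size, matched for read number, had medians within 0.17 to 0.23 for the X and 0.07 to 0.29 for chromosome 4 in 95% of 10000 draws, which treat neighbouring windows as independent. In the hybrid the medians lay closer together, at -0.00 on the X (0.04 with the median window at 0, where the sign turned) and -0.11 on chromosome 4. The X held 20.0% of the melanogaster reads of the mixture (SD 0.247 over 4 lanes) and 17.8% of its sechellia reads (SD 0.784). In the hybrid it held 17.6% and 17.1%. Trans only windows made up 10.5% of the 545 windows on chromosome 4, against 19.2% to 21.7% on the other arms. Windows above both parents made up 2.94% there, against 7.20% on the X and 9.42% to 10.1% elsewhere.

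Neighbouring windows carried similar values. In the 5 windows of 3L 14087001–14092000 together, the log2 ratio was -3.48 in the mixture and -0.55 in the hybrid. In the 6 windows of 3R 19515001–19521000, where the hybrid lay below both parents, it was 2.31 and -0.15. Across 9167 pairs of adjacent windows with at least 200 reads, the Pearson correlation was 0.754 for the mixed ratio, 0.625 for the hybrid ratio and 0.805 for their difference. At 10 kb these had fallen to 0.0893, 0.0761 and 0.171. For the difference between the mixed and separate ratios it was 0.148 at 1 kb.

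**Figure D5:**
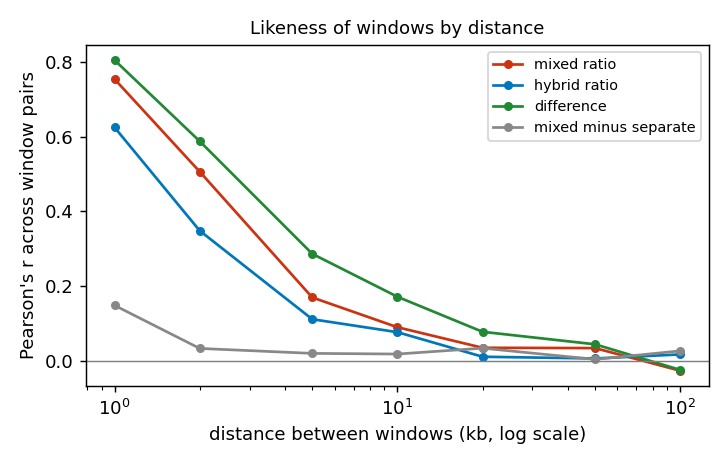
Pearson correlation across pairs of windows with at least 200 reads (y axis) by the distance between them in kb (x axis, log scale), as 1 line each for the mixed ratio, the hybrid ratio, their difference and the mixed minus the separate ratio. At 1 kb the lines stand at 0.754, 0.625, 0.805 and 0.148.

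Lanes of the hybrid and mixed libraries were spread unevenly over a pair of flow cells, FC30B79 and 130MNEAAXX. The hybrid had lane 6 of 130MNEAAXX and lanes 3, 4, 6, 7 and 8 of FC30B79. The mixture had lanes 7 and 8 of 130MNEAAXX and lanes 1 and 2 of FC30B79. Comparisons of the hybrid with the mixture are thus partly confounded with flow cell. In the 2870 windows with at least 1000 reads in both libraries, melanogaster levels of the mixed lanes correlated at 0.991 within FC30B79, at 0.889 within 130MNEAAXX and at 0.929 to 0.936 between the flow cells. The ratio of the species correlated at 0.977, 0.949 and 0.953 to 0.962. Between flow cells, the mixed ratio correlated at 0.932, the hybrid ratio at 0.830 and their difference at 0.800 (Pearson) over the 14837 windows. Spearman values were 0.905, 0.639 and 0.796, and the hybrid ratio had the same sign on both flow cells in 73.1% of the windows. In X 14092001–14094000, 2L 5957001–5961000 and the other windows at least 8-fold below both parents, the median log2 ratio to the nearer parent was -4.09 on 1 flow cell and -4.38 on the other.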

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

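No tests were run in this part, and all of its values were picked out after the data were seen because signals that the comparisons of regulation were not designed to measure, although some lie in tested windows, exceeded the limit that a count of 0 allows.

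In the F1 hybrid, 1176 reads on the mitochondrial sequence were assigned to sechellia, mostly in M 4001–5000 (713) and M 5001–6000 (362), which were among the tested windows. They were picked out as reads of the species that made up little of the hybrid's mitochondrial RNA, since 0.836% (exact 95% interval 0.789% to 0.885%) of its mitochondrial reads carried that assignment. By lane the share ran from 0.507% to 2.89%, and the highest lane was the one on flow cell 130MNEAAXX, with 384 of the 1176 reads.

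The sechellia-alone library held 173267 sechellia reads on the heterochromatic sequence XHet, which the comparisons use only in part. Scaled to the size of each list of sechellia reads, they stood at 8704 CPM, against 1758 in the mixture and 217 in the hybrid. Window XHet 191001–192000 held 103041 of them, against 9032 in the mixture and 295 in the hybrid. Over the lanes of the sechellia-alone library the share of all reads ran from 0.858% to 0.884%. Melanogaster reads on XHet numbered 3984 in the melanogaster-alone library.

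On YHet, a sequence of the Y chromosome in the dm3 assembly, the hybrid library of females held 604 sechellia-assigned reads, at 33.97 CPM of its sechellia reads, against 38.59 in the mixture and 30.99 in the sechellia-alone library. In the hybrid 259 of them lay in YHet 342001–343000 and 210 in YHet 343001–344000, where no library held a melanogaster read.

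With enough reads in both libraries but under 5 reads of 1 species, 327 windows were left out of the tests. Sechellia reads were lacking in 145 and melanogaster reads in 182.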

How the results depend on the processing

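The settings chosen only after the results were seen were fragments counted once, each flow cell alone, the mixed library without lane 8 of flow cell 130MNEAAXX, placed arms only, and positions counted once for the regions beyond both parents. Named windows were followed under 7 alternatives. Of 80 values, 12 on flow cell 130MNEAAXX alone, 4 on FC30B79 alone and 1 without lane 8 had too few reads, and median centring was applied to the 60 values that are not totals. With the separate libraries as parents, 60 values could not change direction, because the hybrid reads are the same or because the windows were named for their side there. Among the other 463 values, 60 under median centring and 80 under no centring had little room to change, since those settings shift all windows alike by a small amount. The flow cell, lane and position settings reuse the reads that chose the windows. Of all 463 values, 459 kept their direction and side of the test and none changed direction, which is therefore no independent support. The remaining 4 were no longer past it, at 2R 20081001–20082000, 3L 9632001–9633000 and 2R 3714001–3715000 on flow cell 130MNEAAXX alone and at U 5293001–5294000 with positions counted once. Their size did not hold under that last setting, where the median absolute log2 value was 3.98 instead of 6.57, and 3L 12124001–12125000 moved from 2.74 to 0.33. It caps a window at its number of positions, and how far the cap and duplicate reads each account for the smaller values was not tested. The ratio of the interquartile ranges of the hybrid totals stayed between 1.81 and 2.30 over the alternatives run and was 2.38 in windows with at least 200 reads. Calls are limited by depth, since 67.8% of windows with at least 200 reads passed the mixed test against 48.8% of all.

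With the median window at 0, the share towards melanogaster became 50.3% for the mixed ratio (62.3% as reported), 51.0% for the hybrid ratio (45.6%) and 44.5% for the difference (62.8%), and the X median of the hybrid ratio became 0.038 (-0.00), by construction of the centring. With no centring the hybrid share was 62.1%. With positions counted once the shares were 55.6% for the hybrid and 46.6% for the difference. That setting left 3882 windows for the hybrid ratio, 4891 for the difference, 1767 cis only, 3759 trans only and 3298 below both parents, with 298 in the same direction, 158 opposing and 372 compensatory, and the cause was not tested. Of the 6972 trans only and 3187 cis only windows, 2721 and 1432 had the same class there. Of 18 named cis only windows, 13 kept that class with the separate libraries and 15 with positions counted once. A minimum of 1 read gave 5772 windows above both, and one of 100 reads 1775 above and 4761 below and a repeat correlation of 0.941, and the cause was not tested.

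Parents from the separate libraries gave 6421 windows above both, and median scaling gave 5136. Limits of 1.5-fold and 2-fold gave 1423 and 410 above and 4182 and 1473 below. The hybrid ratio passed in 6181 windows when at least 1.5-fold was also asked and in 5078 with the beta-binomial test. The normal test used for the difference in that setting gave 7328. Flow cell 130MNEAAXX alone, with fewer reads, gave 10191 windows for the mixed ratio, 2332 for the hybrid ratio, 3725 for the difference, 1094 cis only (667 of them shared), 2641 trans only (1611 shared) and 4818 below both. Flow cell FC30B79 alone gave 4796 trans only windows, 4345 of them among the 6972, and 2501 cis only, 1987 of them among the 3187. Median centring of the gene lists was not run, because no list was analysed.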

Other observations

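Among the tests below, the correlation of adjacent cis only windows, the median over all tested windows and the spread of the mixed ratio in the low windows were chosen only after the result was seen.

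The hybrid total was also tabulated by regulatory class. Of the 6972 trans only windows, 45.5% had a hybrid total like sechellia, 32.1% lay below both parents and 14.2% lay between them. Of the 3187 cis only windows, 38.97% lay between the parents, 30.3% were like sechellia and 3.70% lay below both. Of the 1355 compensatory windows, 22.1% lay above both parents and 22.4% below both. No test of these shares was run, and the class of a window and its total rest on the same mixed reads. The 10 windows with most reads held 5.88% of the hybrid reads, 5.66% of the melanogaster and 7.13% of the sechellia reads of the mixture.

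Windows such as 3L 9082001–9083000 held similar ratios in the mixture and the hybrid, and cis-regulatory divergence may account for them. An assignment bias of single windows was taken to leave adjacent windows unrelated. The hybrid ratio of cis only windows correlated with that of the next tested window at Pearson 0.646 over 2488 pairs. Mates of a fragment can fall in adjacent windows, though, so this correlation does not exclude such a bias. Loss of sechellia reads, as the cause of all large ratios, would put nearly all of them towards melanogaster. Among 683 cis only windows with at least 4-fold hybrid ratios, 57.5% were higher for melanogaster (393 against 290). Loss in part of these windows is not excluded, and 145 windows lacking sechellia reads had been left out beforehand. A loss of melanogaster reads was not tested. A bias that spans a whole gene was not tested and stays open.

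The hybrid total followed the sechellia level more closely than the melanogaster level, with a ratio of interquartile ranges of 2.10. A fault of the mixed library alone would end this with the separate libraries as parents, where the ratio was 2.05. Duplicate reads would end it with positions counted once, where it was 1.90 over 34409 windows. Noisier sequencing of melanogaster reads would widen their differences between flow cells, whose ratio of interquartile ranges was 0.933. Both flow cells carried the mixed library, so noise of the RNA that they shared could not show there. A hybrid expression state closer to that of sechellia is a candidate explanation. A condition of the melanogaster flies that both libraries shared, such as age or tissue make-up, stays open and was not tested.

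In the 60 windows at least 8-fold below both parents, among them 2L 5957001–5958000, 2L 5959001–5960000 and 2L 5960001–5961000, the hybrid held 2605 reads and the mixture 146947. Composition of the hybrid library would lower all windows, but the median log2 ratio to the nearer parent over all tested windows was -0.095. A fault of 1 run would spare 1 flow cell, and the higher of the flow cell medians was -4.09. The windows were chosen as low on the pooled reads, and most hybrid reads came from flow cell FC30B79. This test could therefore hardly have come out otherwise, and it does not exclude such a fault. An RNA source that is larger in melanogaster than in sechellia and nearly missing in the hybrid may account for these windows. Their spread was examined on the premise that 1 source gives 1 common species ratio. The SD of their mixed log2 ratio was 1.04 (bootstrap 95% interval 0.71 to 1.33). This cannot decide the question, because RNAs of 1 source can differ in species ratio. The mixed ratio was towards melanogaster in 57 of the 60 windows and towards sechellia in 3. Without gene names the tissue was not tested.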
